A study of Mus musculus with 6 samples.

How the data were processed

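The deposited values are log2 expression levels that the authors made with RMA, per the submitters' processing notes, which name no version. Per the labels' protocols, liver RNA was isolated with ISOGEN and RNeasy and biotin-labelled cRNA was made from 10 ug of total RNA. The values were used as deposited, with no further normalisation, and their array medians lay between 5.59 and 5.64. Of 45101 probe sets, 64 are controls and 34945 name a single gene. Each of the 18193 genes was represented by its brightest single-gene probe set over the 6 arrays. Gene names were matched to a reference annotation for names only, and 18032 genes were found there.

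Genes were tested with limma 3.58.1 on R 4.3.3 in 1 fit of all 6 arrays with 3 group means, with moderated t tests (residual df 3, prior df 4.24) and Benjamini-Hochberg adjustment within each comparison. A gene is said to change at an adjusted p under 0.05. A level at or under the array medians was not shown to be above background, and a difference from it is a lower bound. SE is the moderated standard error of the log2 difference, and SD is taken over the 2 arrays of a group. All 40 gene lists were fixed before the data were examined, and 39 with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01. Ketogenesis, with 4 measured genes, was not tested. Camera on ranks was added after the data were seen. Camera with a correlation estimated from the data and fry were run beside it, since 3 residual degrees of freedom leave both the estimate and the preset uncertain. Counts "adjusted over the list alone" use the same p values adjusted within the list.

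Genes are named by a rule set beforehand: the 15 largest changes each way among changed genes brighter than the median gene (6.74), or, where fewer than 5 genes changed, the 10 smallest p given as values that did not pass. For fasted Cnot3+/- against fed wild-type the 5 largest each way were taken, and for each list up to 4 members with the smallest p. Cnot3, the measured CCR4-NOT subunits, Pdk4 and Igfbp1 are always given. Pdk4 and Igfbp1 were put on that list from prior knowledge that the study followed them, not from the labels or the values. Genes known only by number or clone name were counted but not named.

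The labels give age, sex, strain, genotype, feeding state and replicate number, and state no pairing. They do not say which part of Cnot3 is missing, so the genotype was taken as labelled. The 3' and 5' control probe sets of 4 transcripts were compared by exact permutation. In a self-test, 200 known changes were put into simulated values with independent noise. In the fasting comparison 67.6% of 2-fold changes and 98.4% of 4-fold changes were recovered, so a change of 2-fold can be missed. These rates need not hold where fewer genes change or where arrays share noise. They are no guide to what was missed between the fasted genotypes, where no gene was called. Figures were drawn with matplotlib 3.10.9 on Python 3.11.15.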

Results

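Gene expression was measured in liver from 8-week-old male C57BL/6J mice on 6 Affymetrix mouse expression arrays. The arrays fall into 3 groups of 2: wild-type mice fed normal chow, wild-type mice kept without food for 24 h, and Cnot3+/- mice kept without food for 24 h. Cnot3 encodes a subunit of the CCR4-NOT complex, which shortens the poly(A) tails of mRNAs and so starts their decay. The labels call the arrays of a group biological replicates, and 2 arrays per group limit the precision of every value given here. The values are RMA log2 levels, and the medians of the arrays lay between 5.59 and 5.64. Over the 18193 genes measured, replicate arrays correlated at r = 0.994 in the fed group, 0.995 in the fasted wild-type group and 0.993 in the fasted Cnot3+/- group; these are correlations across genes, which are not independent replicates. The closest pair of arrays was the second fasted wild-type with the second Cnot3+/- array, at r = 0.996 and with 42 genes at least 2-fold apart. Within the fasted groups 72 genes (wild-type) and 177 genes (Cnot3+/-) lay that far apart, and between the other fasted pairs 113 to 255. The first principal component held 58.7% of the variance and set the fed arrays apart from the fasted arrays. The second, with 16.1%, set the fasted arrays numbered 1 apart from those numbered 2. The design asks what a 24 h fast changes in wild-type liver and what the loss of a Cnot3 allele changes in the fasted liver. No group combines Cnot3+/- with feeding, so the genotype was compared in the fasted state only.

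Cnot3 mRNA was not detectably lower on the arrays labelled Cnot3+/-. The brighter of its 2 probe sets read 9.45 and 9.60 on the fed wild-type arrays, 9.27 and 9.32 on the fasted wild-type arrays, and 9.40 and 9.16 on the arrays labelled Cnot3+/-. The difference between the fasted groups was -0.01 (log2, SE 0.13), with a 95% confidence interval from -0.34 to 0.31 whose lower end stands for 0.792 of the wild-type level. The dimmer probe set differed by -0.08 (interval -0.51 to 0.34). The labels do not say which part of the gene was removed, and a probe set outside that part checks nothing, so the genotype is given here as labelled. None of the 10 measured CCR4-NOT subunits passed the test for fasting or for genotype. Cnot6, a catalytic subunit, had the smallest fasting p among them, with a log2 difference of -0.43 (SE 0.11, limma adjusted p = 0.0787). Cnot7, another catalytic subunit, differed by -0.24 (adjusted p = 0.476), but by 0.68 (adjusted p = 0.047) when probe sets shared between transcripts were left out.

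In fasted wild-type liver, lists of fat and sterol synthesis genes were lower and those of fatty acid oxidation and PPARalpha signalling higher in camera with a preset correlation. With an estimated correlation none of these 4 lists was called (adjusted p = 0.133 for lipogenesis and 0.199 for the others), while fry called all 4. In limma's test with Benjamini-Hochberg adjustment at 0.05, 913 of 18193 genes changed, 340 of them up and 573 down. A change of at least 2-fold was seen in 387 of them, 133 up and 254 down. Among the largest falls was that of Hsd3b5, a male-biased steroid dehydrogenase of hepatocytes, from 11.96 ± 0.17 to 4.82 ± 0.50 (mean ± SD, n = 2 arrays in each group), a log2 difference of at least 7.14 (SE 0.23, adjusted p = 9.63e-05). Among the largest rises was that of Cidec, which encodes a lipid droplet protein, from 5.35 ± 0.73 to 11.15 ± 0.61, a log2 difference of at least 5.80 (SE 0.52, adjusted p = 0.00308). The lower level of both genes lies under the array medians and was not shown to be above background, so these differences are lower bounds with no exact fold or rank. Also among the 15 largest rises were the cell cycle inhibitor Cdkn1a (log2 3.12, SE 0.18), the carnitine transporter Slc22a5 (2.40, SE 0.13) and the sterol 12-alpha-hydroxylase Cyp8b1 (2.38, SE 0.13). The 15 largest falls included Cyp2c70 (log2 -4.96, SE 0.23) and the organic anion transporter Slc22a7 (-3.53, SE 0.28). All 913 changed genes had non-overlapping groups, a state that chance gives to 33.3% of genes with 2 arrays against 2 and that 50.8% of all genes showed.

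**Figure D1:**
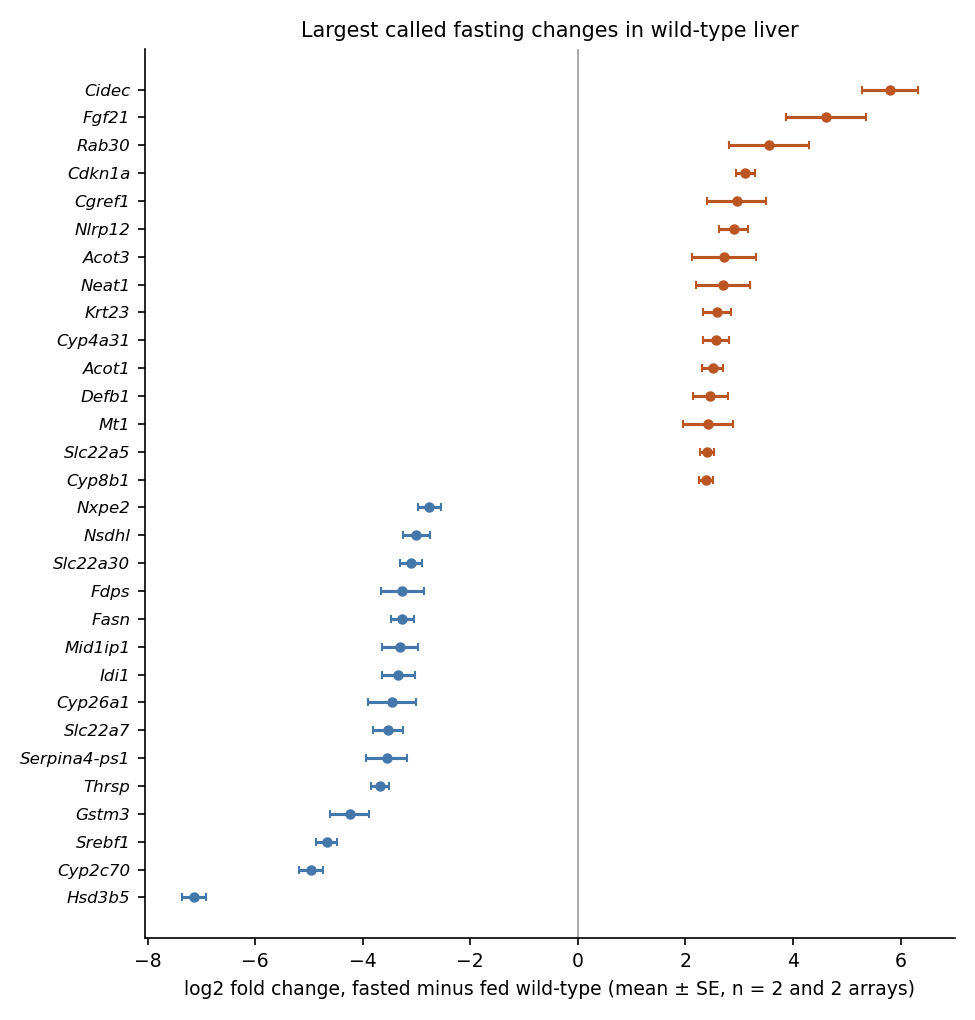
Log2 fold change between fasted and fed wild-type liver for the 15 named genes with the largest rise and the 15 with the largest fall among changed genes brighter than the median gene; points are the fitted difference of 2 arrays against 2 and bars the standard error. The values of Cidec, Fgf21 and Hsd3b5 are lower bounds, since the dimmer group lies at or under the array medians.

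In the lipogenesis list, 13 of 24 measured genes fell and 1 rose (20 and 2 adjusted over the list alone), with a median log2 change of -1.02 (camera adjusted p = 3.4e-16; adjusted p = 0.133 with an estimated correlation). Srebf1, the transcription factor that drives the pathway, fell from 13.27 ± 0.34 to 8.60 ± 0.19 (log2 -4.67, SE 0.19, adjusted p = 0.000252). Thrsp fell by 3.68 (SE 0.16), fatty acid synthase Fasn by 3.27 (SE 0.21) and ATP citrate lyase Acly by 2.34 (SE 0.13). The gene that rose was Elovl5, a fatty acid elongase (log2 0.59). Cholesterol synthesis genes fell likewise: 14 of 20 passed the test, all downward (17 adjusted over the list alone), with a median of -1.61 (camera adjusted p = 3.24e-19; adjusted p = 0.199 with an estimated correlation). Idi1 fell by 3.33 (SE 0.30), lanosterol synthase Lss by 1.80 (SE 0.14) and Dhcr7 by 1.66 (SE 0.14). Fdps fell by 3.26 (SE 0.40) on its brighter probe set, while its other probe set had the opposite sign.

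Among 26 measured PPARalpha targets, 14 rose and 0 fell (21 and 0 adjusted over the list alone), with a median log2 change of 1.37 (camera adjusted p = 1.24e-17; adjusted p = 0.199 with an estimated correlation). The acyl-CoA thioesterase Acot1 rose by 2.51 (SE 0.19), the fatty acid transporter Slc27a1 by 2.18 (SE 0.14) and the glucose uptake regulator Txnip by 1.74 (SE 0.16). Fgf21, a fasting hormone made by the liver, rose by at least 4.62 (SE 0.74, adjusted p = 0.0194), as its fed level lies at the array medians; its adjusted p was 0.0815 without fed replicate 1, 0.0886 without fed replicate 2 and 0.0956 without fasted wild-type replicate 2. Of 25 beta oxidation genes, 13 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 7.22e-14; adjusted p = 0.199 with an estimated correlation). Cpt1a, which carries out the rate-limiting step of mitochondrial fatty acid entry, rose from 12.14 ± 0.07 to 13.58 ± 0.12 (log2 1.44, SE 0.14, adjusted p = 0.00377). Ehhadh and Cpt2 rose by 1.26 (SE 0.15) and 0.95 (SE 0.12). Ketogenesis was not tested as a list because 4 of its genes were measured.

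Genes that answer to insulin and glucocorticoids shifted upward as groups. These lists share Cdkn1a, Pck1, Mt1 and Mt2, and the FoxO list shares Pdk4 and Txnip with the PPARalpha targets, so their calls are not independent. Among 31 genes of the FoxO and insulin response, 8 rose and 0 fell (13 and 2 adjusted over the list alone), with a median of 0.77 (camera adjusted p = 1.56e-06; adjusted p = 0.199 with an estimated correlation). The median was 0.36 without fed replicate 2. Besides Cdkn1a and Txnip, these included the triglyceride lipase Pnpla2, which rose by 1.79 (SE 0.16, adjusted p = 0.00308). Of 18 glucocorticoid response genes, 3 rose (Cdkn1a, Fkbp5 and Mt1) and 1 fell (Nr3c1, the glucocorticoid receptor itself), and 17 of 18 differences were positive (6 up and 1 down adjusted over the list alone; median 0.98, camera adjusted p = 2.36e-05; adjusted p = 0.389 with an estimated correlation). The median was 0.28 without fed replicate 2 and 1.22 without fed replicate 1, and fry did not call the list (adjusted p = 0.1). Mt1 differed by 0.38 (adjusted p = 0.426) without probe sets shared between transcripts, and neither Mt1 nor Nr3c1 passed with the mean over probe sets (0.0636 and 0.118). Of 16 gluconeogenesis genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 0.00015; adjusted p = 0.199 with an estimated correlation). Without fed replicate 2 the median was 0.22. The 4 were Creb3l3, Got1, Gpt2 and Pcx, with log2 changes from 0.56 to 1.18. The fed arrays differed from each other at several of these genes: Igfbp1 read 12.26 on fed replicate 1 and 8.33 on fed replicate 2, and Pck1, the rate-limiting gluconeogenic enzyme, 13.93 and 11.74. Igfbp1, an insulin-repressed secreted protein, and Pdk4, a brake on glucose oxidation, did not pass in the fasting test: the log2 difference was 2.94 for Igfbp1 (SE 1.06, adjusted p = 0.189) and 1.39 for Pdk4 (SE 0.74, adjusted p = 0.375). Without fed replicate 1 the difference of Igfbp1 was 4.91. The fasted wild-type mean of Igfbp1, 13.24, lay much nearer to fed replicate 1 than to fed replicate 2, so the difference shrinks without fed replicate 2.

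Detoxifying and male-biased genes of hepatocytes shifted downward as groups. Of 32 xenobiotic metabolism genes, 8 fell and 1 rose (15 and 2 adjusted over the list alone), with a median of -0.39 (camera adjusted p = 1.06e-06; adjusted p = 0.199 with an estimated correlation). The glutathione S-transferases Gstm3, Gstm2 and Gsta4 fell by 4.24 (SE 0.37), 1.77 (SE 0.12) and 1.60 (SE 0.15); the gene that rose was the nuclear receptor Nr1i3 (log2 0.86). Of 19 growth hormone and male-biased genes, 6 fell and 1 rose (9 and 2 adjusted over the list alone), with a median of -0.53 (camera adjusted p = 1.97e-05; adjusted p = 0.389 with an estimated correlation). The falls included Hsd3b5, the bile acid transporter Slco1a1 (log2 -2.12, SE 0.24) and Nudt7 (-1.49, SE 0.16), and the rise was that of Elovl3 (1.22). Bile acid genes moved both ways, with 3 up and 3 down among 22 (camera adjusted p = 0.333): Cyp8b1 rose and Slco1a1 fell, as did the bile salt export pump Abcb11 (log2 -1.34, SE 0.18).

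Smaller shifts were called in lists of cell maintenance. Proteasome genes had a median of 0.27, and 26 of 31 differences were positive, with 1 gene, Psmd4, past the test for single genes (camera adjusted p = 5.03e-05; adjusted p = 0.567 with an estimated correlation). Without fasted wild-type replicate 2 the median was 0.18, and fry did not call the list (adjusted p = 0.185). In the autophagy and proteolysis list 5 of 24 genes rose, among them Map1lc3b (log2 0.95, SE 0.14) and Bnip3 (0.63, SE 0.11), for a median of 0.14 (camera adjusted p = 0.0192; adjusted p = 0.481 with an estimated correlation). The list was not called by fry (adjusted p = 0.0621) or by camera on ranks (0.0887), and its median was 0.06 without fasted wild-type replicate 2. In the cell cycle list Mcm6, Mcm5 and Rrm2 fell, and the median over 29 genes was -0.17 (camera adjusted p = 0.00175; adjusted p = 0.199 with an estimated correlation). It was -0.10 without fed replicate 2, and the list was not called among genes above the median level (adjusted p = 0.0616). Immediate early genes had a median of 0.25 with 2 of 26 genes up, Zfp36 and Gadd45b (camera adjusted p = 0.0163; adjusted p = 0.494 with an estimated correlation). Heat shock genes had a median of 0.34 with none of 15 genes past the test (camera adjusted p = 0.0237), and oxidative phosphorylation genes a median of -0.07 with 1 of 46 genes down, Cox7c (camera adjusted p = 0.021); both gave an adjusted p = 0.494 with an estimated correlation. These last 3 list calls did not hold on every set of arrays. The immediate early call was lost without fed replicate 2 and without fasted wild-type replicate 2, and its median ran from 0.12 to 0.46 with single arrays left out. The heat shock call was lost without fed replicate 1 and without fasted wild-type replicate 1. The oxidative phosphorylation call was lost without fed replicate 2 and without fasted wild-type replicate 1. It was also lost after cyclic loess (camera adjusted p = 0.0609), after centring on the brighter genes (0.0507) and among genes above the median level (0.227). Fry called none of the 3 lists (adjusted p = 0.21 for immediate early, 0.257 for heat shock and 0.1 for oxidative phosphorylation genes).

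Lists that were not called held some strongly changed genes. Of 26 ER stress genes, 3 fell, Sdf2l1 (log2 -1.74, SE 0.16), Pdia6 and Edem1, while Trib3 on the same list differed by 1.53 (adjusted p = 0.06); the list as a whole gave a camera adjusted p of 0.0896. Of 12 glycolysis genes, Ldha rose (0.95, SE 0.12) and Pklr and Khk fell (camera adjusted p = 0.439). The liver glycogen phosphorylase Pygl fell by 0.77 (SE 0.11) in the glycogen list (adjusted p = 0.0888), and 3 of 31 urea cycle and amino acid catabolism genes rose: Asl, Mat1a and Got1 (adjusted p = 0.168). In the acute phase list Lbp, Serpina3n and Cebpd rose and Apcs and Steap4 fell; its median was -0.04 and its mean 0.00, and camera's direction was up (adjusted p = 0.94). Of 39 mRNA decay factors outside the CCR4-NOT complex, Zfp36 and Zfp36l2, which bind AU-rich elements, rose by 0.96 (SE 0.15) and 1.25 (SE 0.22), and Lsm6 fell by 0.98 (SE 0.16; list adjusted p = 0.484). No gene of the 42 measured cytosolic ribosomal proteins passed (adjusted p = 0.157).

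Among the cell type lists, macrophage and Kupffer cell genes had 14 of 15 positive differences after fasting and a median of 0.37, with no gene past the test over all genes and 3 adjusted over the list alone (camera adjusted p = 0.00128, and 0.561 with an estimated correlation). Fry did not call this list (adjusted p = 0.257). Stellate cell and fibroblast genes had a median of -0.18 (camera adjusted p = 0.0456; adjusted p = 0.494 with an estimated correlation), with Col3a1 (log2 -2.32, SE 0.34), Lrat (-1.20, SE 0.13), Tagln and Col1a1 down and Dcn up. That call was lost without fed replicate 1 (adjusted p = 0.213) and without fasted wild-type replicate 2 (0.121), and the median was -0.41 without fed replicate 2. It was also lost after cyclic loess (0.0764), among genes above the median level (0.468), without probe sets shared between transcripts (0.12), by fry (0.105) and by camera on ranks (0.146). Endothelial, lymphocyte, neutrophil, erythroid, adipocyte, cholangiocyte, exocrine pancreas and skeletal muscle lists were not called, with adjusted p values from 0.387 to 0.875. Single genes on them changed, such as the endothelial receptor Lyve1 (log2 1.58, SE 0.17) and Cela1 (-1.45, SE 0.13). The exocrine pancreas list had a median of 0.12 and a mean of -0.03.

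The number of changed genes depended on single arrays: it was 458 without fed replicate 1, 287 without fed replicate 2, 137 without fasted wild-type replicate 1 and 193 without fasted wild-type replicate 2. Of 39 gene lists, camera with a preset correlation called 17, fry called 10 (9 of them also called by camera, and hepatocyte secreted proteins besides), and camera with an estimated correlation called 0.

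**Figure D2:**
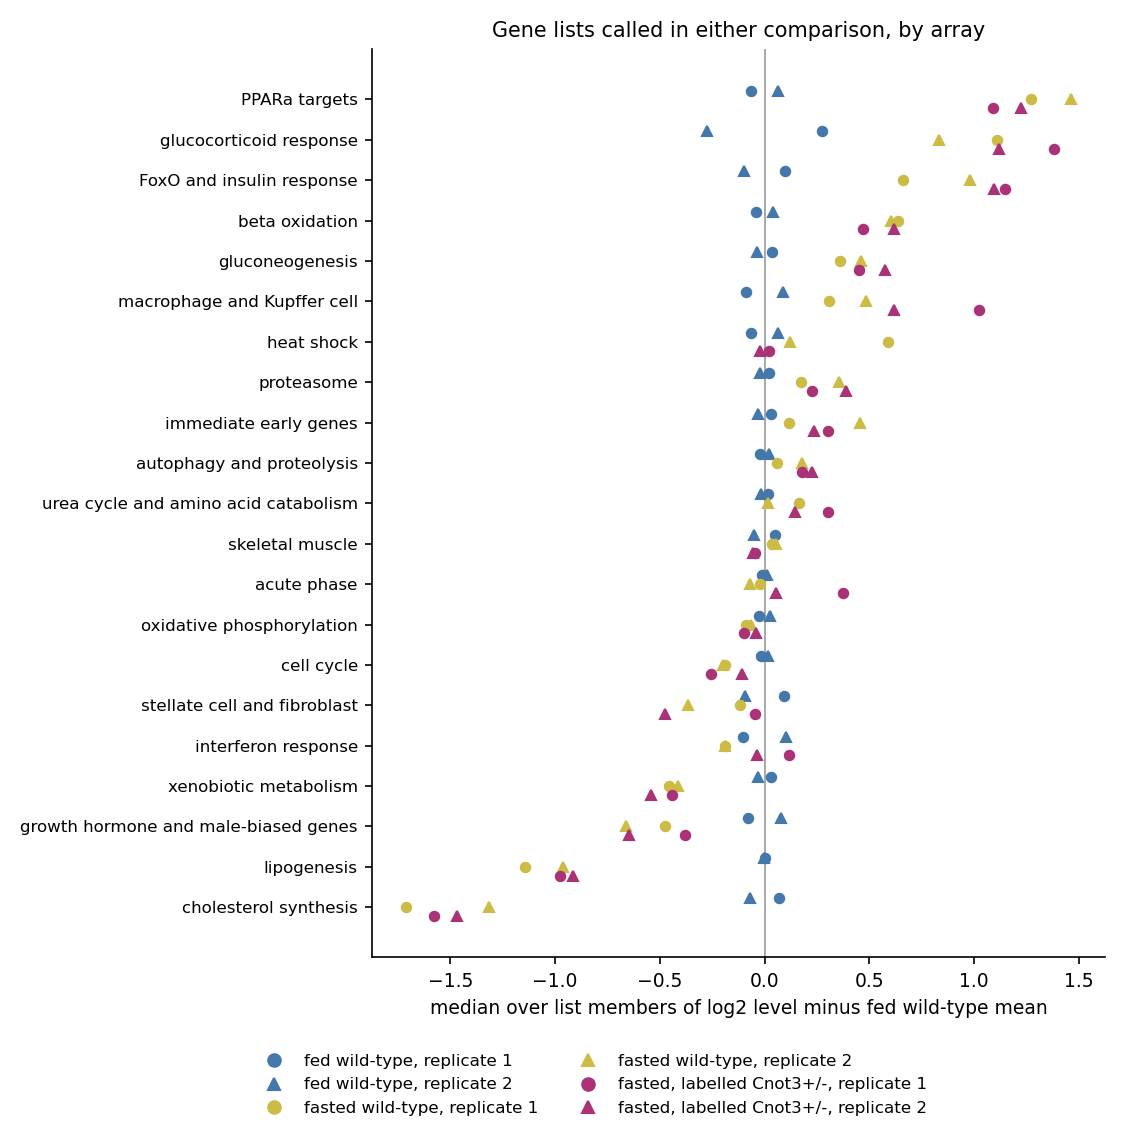
Median over list members of the log2 level minus the fed wild-type mean, on each of the 6 arrays, for lists called by camera in either comparison; circles are replicate 1 and triangles replicate 2. Lipogenesis and cholesterol synthesis lie below 0 on all 4 fasted arrays, PPARalpha targets and beta oxidation above it, and the macrophage and Kupffer cell list is highest on the first array labelled Cnot3+/-, at 1.03.

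In fasted liver, no gene passed the test between the arrays labelled Cnot3+/- and wild-type. Camera with a preset correlation called 8 of 39 lists, with macrophage, acute phase, interferon and FoxO response genes higher on the Cnot3+/- arrays and chaperone genes lower, but none was called with an estimated correlation (smallest adjusted p = 0.874) or by fry (0.803). The directions rest on the labels, which the Cnot3 probe sets do not check. limma called 0 of 18193 genes, with or without a variance trend; 1011 genes had an unadjusted p under 0.05 (997 with the trend), against 910 by chance, and 40 genes differed by 2-fold or more. The smallest p belonged to Dnaic1, an axonemal dynein chain, at 7.54 in wild-type and 6.19 on the Cnot3+/- arrays (log2 -1.35, SE 0.11, adjusted p = 0.0963). Sult1e1, the estrogen sulfotransferase, read 6.18 ± 0.23 in wild-type and 8.87 ± 0.87 on the Cnot3+/- arrays (mean ± SD, n = 2 arrays in each group), a 6.44-fold difference (log2 2.69, SE 0.35, adjusted p = 0.438). Ddit4, an inhibitor of mTORC1 signalling, differed by 1.43 (SE 0.21, adjusted p = 0.766) and the autophagy gene Wipi1 by 0.77 (SE 0.13, adjusted p = 0.863). The other 6 of the 10 genes with the smallest p were Fmn2, Snhg11, Ofd1, Gstm2, Cpne8 and Atp10d, all higher on the Cnot3+/- arrays by 0.67 to 1.22; the wild-type level of Ofd1 lies under the array medians, so its difference is a lower bound. Gstm2 had fallen on fasting, and Snhg11 read 6.98 in fed, 5.71 in fasted wild-type and 6.92 in fasted Cnot3+/- liver.

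**Figure D3:**
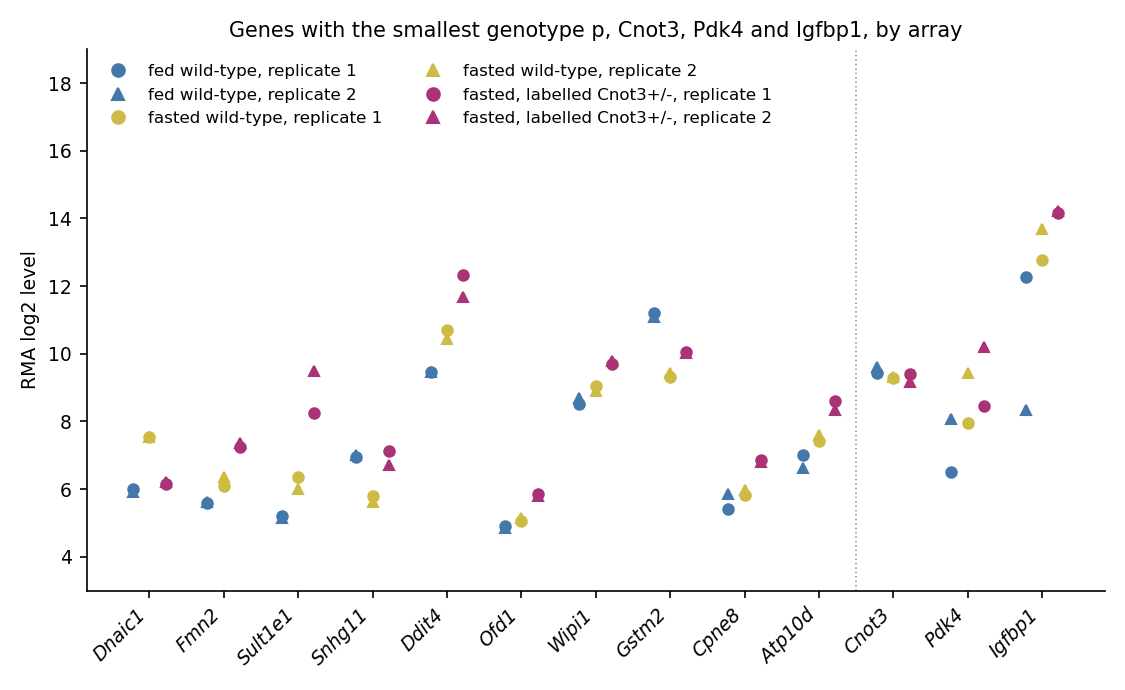
RMA log2 levels on each array of the 10 genes with the smallest p between the fasted groups and, right of the dotted line, of Cnot3, Pdk4 and Igfbp1; circles are replicate 1 and triangles replicate 2. Sult1e1 lies at 6.18 on average in fasted wild-type and at 8.87 on the arrays labelled Cnot3+/-, whereas the 6 values of Cnot3 lie between 9.16 and 9.60.

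In the macrophage and Kupffer cell list 14 of 15 differences were positive, with a median of 0.44 (camera adjusted p = 1.27e-07; adjusted p = 0.874 with an estimated correlation). The haemoglobin scavenger receptor Cd163 differed by 1.04 (SE 0.27), Marco by 0.66 (SE 0.24) and the complement genes C1qa and C1qb by 0.49 (SE 0.17) and 0.48 (SE 0.16), none of them past the test. Against the mean of the fasted wild-type arrays, the list median was 0.71 on the first Cnot3+/- array and 0.22 on the second, and without the first the camera adjusted p was 0.0393. In the acute phase list 27 of 28 differences were positive (median 0.19, camera adjusted p = 1.47e-06; adjusted p = 0.874 with an estimated correlation). These included the serum amyloid gene Saa2 (1.30, SE 0.46), Apcs (2.01-fold) and Stat3 (0.47, SE 0.13). The call was lost without the first Cnot3+/- array, where the median was 0.10, and the median was 0.36 without the second. In the interferon list 21 of 27 differences were positive (median 0.19, camera adjusted p = 0.00049, and 0.874 with an estimated correlation), led by Oas1a (0.59, SE 0.15) and Usp18 (0.83, SE 0.21). The interferon call was lost without the first Cnot3+/- array and without fasted wild-type replicate 2. Its median ran from 0.07 to 0.28 with single arrays left out.

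The FoxO and insulin response list was also higher on the Cnot3+/- arrays, with 24 of 31 differences positive and a median of 0.23 (camera adjusted p = 0.000245; adjusted p = 0.874 with an estimated correlation). Adjusted over the list alone 2 genes passed, Ddit4 and Txnip, the latter with a difference of 0.76 (SE 0.16). The call held without each array in turn, with adjusted p values up to 0.0393. Glucocorticoid response genes, which include Mt2 and other members of the FoxO list, had a median of 0.08 and a mean of 0.42, with 12 of 18 differences positive (camera adjusted p = 0.0423, and 0.896 with an estimated correlation). Sult1e1 and the metallothionein Mt2 (1.72, SE 0.49) had its smallest p values, and the call was lost without the first Cnot3+/- array (adjusted p = 0.55, median -0.01), without fasted wild-type replicate 2 (0.365), after cyclic loess (0.0589), among genes above the median level (0.143), with the mean over probe sets (0.189) and by camera on ranks (0.135). Urea cycle and amino acid catabolism genes had 26 of 31 positive differences (median 0.11, camera adjusted p = 0.0423; adjusted p = 0.929 with an estimated correlation). That call was lost without either fed array and without fasted wild-type replicate 2 or the first Cnot3+/- array, where camera's direction was down. It was also lost after centring on the brighter genes (camera adjusted p = 0.0625) and among genes above the median level (0.338). The same held with the mean over probe sets (0.0524) and without probe sets shared between transcripts (0.0962).

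Of 15 heat shock genes, 14 had negative differences and none passed the test (median -0.30, camera adjusted p = 0.00268; adjusted p = 0.874 with an estimated correlation), such as Dnajb4 (-0.42, SE 0.12). The fasted wild-type arrays lay apart at this list, at 0.13 and -0.13 around their mean. The call was lost without fasted wild-type replicate 1 and without Cnot3+/- replicate 2, and the median ran from -0.39 to -0.14 with single arrays left out. Skeletal muscle genes, dim in liver, had 11 of 12 negative differences and a median of -0.10 (camera adjusted p = 0.0402; adjusted p = 0.874 with an estimated correlation). The call was lost without any single fasted array, with adjusted p values from 0.0532 to 0.216. The 4 lists with the smallest camera p for fasting were not called between genotypes: lipogenesis had a median of 0.07 (adjusted p = 0.953), cholesterol synthesis -0.12 (0.35), beta oxidation -0.05 (0.413) and PPARalpha targets -0.11 (0.0614). PPARalpha targets were called lower with a variance trend (adjusted p = 0.0226), among genes above the median level (0.00286), by camera on ranks (0.0415) and without 4 of the 6 arrays in turn (0.00713 to 0.0424), and cholesterol synthesis without fasted wild-type replicate 1 (median -0.24, adjusted p = 0.000287). Endothelial genes had 10 of 13 negative differences (median -0.15, adjusted p = 0.0675), and the list was called without Cnot3+/- replicate 2 (0.00387) and after cyclic loess (0.0301). The CCR4-NOT list had a median of 0.08 (adjusted p = 0.305) and the other mRNA decay factors 0.04 (adjusted p = 0.586).

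Pdk4 and Igfbp1 did not differ detectably between the fasted genotypes. Pdk4, which shuts off pyruvate dehydrogenase, read 7.94 and 9.43 on the fasted wild-type arrays and 8.46 and 10.20 on the Cnot3+/- arrays, a difference of 0.64 (SE 0.74, adjusted p = 0.922). Igfbp1 averaged 13.24 on the fasted wild-type and 14.2 on the Cnot3+/- arrays, a difference of 0.96 (SE 1.06, adjusted p = 0.917). That SE is pooled over all 3 groups and includes the fed arrays, which lay apart at 12.26 and 8.33. It is therefore no measure of the spread of Igfbp1 in the fasted livers alone. A fit of only the 2 fasted groups called 0 genes. In all 3 groups the array numbered 2 was the higher for Pdk4, at 6.51 and 8.08 in the fed group. In both fasted groups it was also the higher for Fgf21, at 9.32 and 11.14 in wild-type and 8.50 and 10.62 in Cnot3+/-.

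The first Cnot3+/- array carried much of the macrophage, acute phase and interferon shifts. It also had the largest 3' minus 5' difference for 3 of 4 control transcripts, a sign of lower RNA integrity. For Actb the difference was 1.06 on that array and 0.53 on the other Cnot3+/- array, against 0.58 and 0.43 on the fasted wild-type arrays. For Gapdh it was 0.31 and 0.06, against -0.02 and -0.14, and for Pcx 4.12 and 2.81, against 2.67 and 1.87. The exact 2-sided permutation test gave p = 0.667 for Actb and p = 0.333 for Gapdh, Pcx and Tfrc between these groups. The smallest p that 2 arrays against 2 allow is 0.333. Between fasted and fed wild-type, the means of all 4 controls were lower in the fasted group, such as 2.27 against 3.27 for Pcx. The same permutation test gave p = 0.333 for Actb, Pcx and Tfrc and p = 0.667 for Gapdh there. Of 39 lists camera called 8 between the genotypes, 6 up and 2 down, while fry and camera with an estimated correlation each called 0; without the first Cnot3+/- array or fasted wild-type replicate 2 camera called 4. Single genes passed when an array was left out: Sult1e1 without the first Cnot3+/- array (log2 3.30, adjusted p = 0.017), and Fst and Moxd1 without the second (adjusted p = 0.00883 for both, named here after their values were seen).

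**Figure D4:**
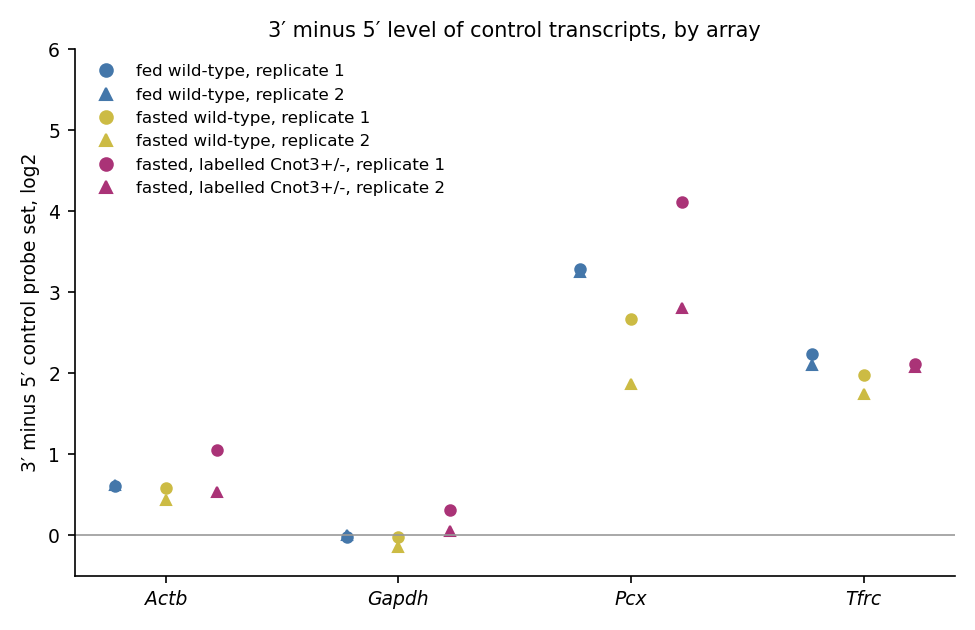
Difference in log2 level between the 3' and 5' control probe sets of Actb, Gapdh, Pcx and Tfrc on each array; circles are replicate 1 and triangles replicate 2. The first array labelled Cnot3+/- is the highest of the 6 for Actb (1.06), Gapdh (0.31) and Pcx (4.12).

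Against fed wild-type, the fasted Cnot3+/- arrays showed much of the wild-type fasting pattern. limma called 1375 genes, 706 up and 669 down. All of them had non-overlapping groups, which follows largely from passing the test and which 48.0% of all genes showed. Among the largest falls were again Srebf1 (log2 -4.57, SE 0.19), Cyp2c70 (-4.43, SE 0.23) and Gstm3 (-4.09, SE 0.37). Hsd3b5 fell by at least 6.83 (SE 0.23) and Cidec rose by at least 5.87 (SE 0.52), since their dimmer groups lie under the array medians. The same holds for Sult1e1, which rose by at least 3.69 (SE 0.35, adjusted p = 0.00254). Mt2 rose by 3.70 (SE 0.49, adjusted p = 0.00711). Cnot6 passed narrowly (log2 -0.47, SE 0.11, adjusted p = 0.0487), and did not when any single array was left out (adjusted p from 0.0978 to 0.166). Of the genes changed in wild-type fasting, 299 were also up and 460 also down here, where independent lists would share 13.2 and 21.1. In 20 simulations with noise alone in all 3 groups, the comparisons shared at most 1 gene up and 0 down. Noise alone gives almost no calls to share, so these simulations cannot show how much the common fed arrays add to the overlap. The 2 fed arrays were not split between the comparisons, which would leave 1 array in each, so part of this overlap may come from the fed arrays that both comparisons use. This comparison joins fasting and genotype, and whether the genotypes respond to fasting differently was not tested, since the design has no fed Cnot3+/- group. The count was 743 without fed replicate 1, 597 without fed replicate 2, 857 without either fasted wild-type array, 929 without the first Cnot3+/- array and 696 without the second.

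Over 18193 genes the fasting change in wild-type and the difference between the fasted Cnot3+/- and wild-type arrays correlated at r = -0.08 (rho = -0.19), across genes that are not independent replicates. Both use the fasted wild-type arrays, with opposite sign, and 100 simulations of unchanged groups with independent noise gave r = -0.50 on average, or -0.19 with the fasting effects kept. With the correlation of 0.454 between same-numbered fasted arrays put into the noise and the fasting effects kept, they gave -0.10 (range -0.13 to -0.07), which holds the observed r. These linked simulations also scaled the noise of each group to its own spread, by 1.18 (fed), 1.05 (fasted wild-type) and 1.29 (Cnot3+/-). The covariance was -0.00688, against -0.0142 in the simulations without effects. Of the 913 fasting genes, 459 (50.3%) differed back toward the fed level on the Cnot3+/- arrays, 129 of 340 that rose and 330 of 573 that fell, and 454 differed further away. The simulations with independent noise gave 62.8% (range 60.8 to 65.0%). None of the 913 genes was called between the genotypes. Without single arrays r was -0.23 (without fasted wild-type replicate 1) and -0.21 (without fasted wild-type replicate 2). It was 0.089 without the first Cnot3+/- array and -0.195 without the second.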

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

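Probe sets that name no single gene were tested apart from the genes, 10092 of them. In fasted against fed wild-type liver 24 changed, 8 up and 16 down. In fasted Cnot3+/- against fed wild-type liver 54 changed, 28 up and 26 down. Between the fasted genotypes 0 changed.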

How the results depend on the processing

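The number of genes changed by fasting was 913 and lay between 802 and 1206 under other settings; it was 387 with a 2-fold threshold and ran from 137 to 1033 when single arrays were left out. For fasted Cnot3+/- against fed wild-type the count of 1375 became 523 with the 2-fold threshold, 857 when only the 2 groups compared were fitted, and 597 to 929 when single arrays were left out. Between the fasted genotypes 0 genes were called, and 0 to 2 with single arrays left out.

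Camera called 17 lists for fasting and 8 for genotype. With an estimated correlation it called 0 and 0, and fry called 10 and 0. With single arrays left out it called 15 to 18 for fasting and 4 to 8 for genotype. The urea cycle and amino acid catabolism list, with a genotype median of 0.11, reversed without fasted wild-type replicate 2 (median -0.0058) and in camera's direction without Cnot3+/- replicate 1 (median 0.019), and reached 0.178 without fasted wild-type replicate 1. Cnot7 reversed to 0.68 in the fasting comparison without probe sets shared between transcripts.

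Of 95 named genes called for fasting, 37 kept the call under every alternative. Across named genes and single arrays left out, the fasting result stayed the same 821 times, was weaker 190 times and stronger 27 times; under the other alternatives it stayed the same 1267 times, was weaker 29 times, stronger 54 times and reversed 1 time. For the lists the counts with single arrays left out were 220 the same, 8 weaker and 6 stronger for fasting, and 212 the same, 13 weaker, 7 stronger and 2 reversed for genotype; under the other alternatives they were 344, 35 weaker and 5 stronger, and 390, 27 weaker and 6 stronger. Where leaving out an array left 1 in a group, that array was assumed to vary like the others.

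The correlation between the fasting and genotype changes, -0.084, ran from -0.23 to 0.089 with single arrays left out, and the share of fasting genes that differed back, 50.3%, from 41.7 to 61.0%. The Actb 3' minus 5' difference of Cnot3+/- replicate 1 was 1.06 before and after cyclic loess.

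With the replicate number as a replicate block, 1206 genes were called for fasting, 0 for genotype and 1708 for fasted Cnot3+/- against fed wild-type, and 16 and 8 lists. A replicate block on the 4 fasted arrays alone, an alternative added after the data were seen, called 18 genes for genotype, 11 up and 7 down. With the replicate block over all 6 arrays the fasting difference of Pdk4, 1.39, passed (adjusted p = 0.0042). Deviations of same-numbered arrays correlated at 0.454 between the fasted groups, and at 0.0447 and -0.0093 between the fed and each fasted group. The labels state no pairing, so these calls are not used in the report.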

Other observations

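The causes weighed in this part, and the values set against them, were chosen after the results were seen. The gene lists and their camera and fry tests were planned, as was leaving out single arrays. Some genes differed the same way between the arrays numbered 1 and 2 in both fasted groups; those given here were named after their values were seen, and no list was tested for this. Atf3 read 6.27 and 8.02 on the fasted wild-type arrays and 5.75 and 8.43 on the Cnot3+/- arrays, and Psat1 4.31 and 6.52, and 4.05 and 6.91. Hspa1b ran the other way, at 13.51 and 11.23, and 12.60 and 10.06. Over all genes the deviations of same-numbered fasted arrays correlated at r = 0.454, across genes that are not independent replicates.

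Macrophage and Kupffer cell genes were called higher on the arrays labelled Cnot3+/- by camera with a preset correlation, but not with an estimated correlation (adjusted p = 0.874) or by fry (0.803), and 0 of 15 members passed. If the lower RNA quality of the first Cnot3+/- array were the whole cause, the list should not be called without it; the call held with an adjusted p of 0.0393, but with 1 Cnot3+/- array left this cause and a genotype effect cannot be told apart. A lower share of hepatocytes should raise the genes of every other cell type alike. The endothelial median was -0.15, that of stellate cells 0.08 and that of lymphocytes 0.06. The Kupffer mean exceeded the means of these lists by 0.60 (SE over members 0.11), 0.39 (0.088) and 0.34 (0.093). These SEs are over genes of the same arrays and do not measure the spread between livers. By array, the endothelial median was -0.22 and -0.06 on the Cnot3+/- arrays, below the wild-type values of -0.03 and 0.03. The Kupffer medians lay above wild-type on both. These values go against that cause on these arrays, but 2 arrays per group cannot exclude it. Counting macrophages in sections of more Cnot3+/- and wild-type livers would decide between more cells and more mRNA per cell.

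The fed wild-type arrays lay apart at insulin and glucocorticoid genes. RNA quality differing between them is an unlikely cause, since their Actb values differed by 0.0195. The state of a 24 h fast in the first fed mouse is unlikely too, though a shorter time without food stays open. The mean difference over lipogenesis genes was -0.0097 (SE over members 0.145), against a mean fasting change of -1.30. This SE is over genes of the same arrays and does not measure the spread between livers. A different time of day stays open. The clock gene index is the mean of Nr1d1, Nr1d2, Dbp and Ciart minus that of Arntl, Clock, Cry1 and Npas2. It differed by 1.33 between the fed arrays and by 0.24 and -0.64 within the fasted groups. The index was 2.49 on fed replicate 1 and 1.16 on fed replicate 2, against 1.71 to 2.34 on the fasted arrays. Fed replicate 1 thus lay nearer to the fasted arrays, so the index cannot tell time of day from food intake. Collecting fed livers at fixed hours would test the time of day.

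Fasting genes differed back toward the fed level on the Cnot3+/- arrays less often than independent noise gives. Noise shared by same-numbered fasted arrays may explain part of the covariance of the changes, which was -0.00688 against -0.00681 in simulations with such linked noise. Those simulations also scaled the noise to the spread of each group, which the simulations with independent noise did not. The match therefore does not rest on the link alone, and the link was not simulated without the scaling. The share of genes was 50.3%, and the lowest share with linked noise was 54.0%, a gap that rests on the assumed noise model, so shared noise and a genotype effect cannot be told apart here. Arrays from fed Cnot3+/- mice and more fasted mice of both genotypes, with the order of handling recorded, would separate these causes.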
